A study of Mus musculus with 4 samples.

How the data were processed

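Total RNA of mouse lungs at E18.5 was labelled with Cy3 for wild type pools and Cy5 for Fgf8 hypomorph pools, per the labels, each pool holding 3 lungs, and hybridised to 4 two-colour Agilent arrays. The 4 arrays lay on 1 slide and were read in 1 scan, so no slide or scan block applied, and no array had its dyes exchanged. The mice were of a mixed strain background, per the labels. The 4 replicates were separate pools, per the labels, and shared no animal as far as the labels say.

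Spots were read with Agilent Feature Extraction 9.5.1, per the submitters' processing notes. The deposited mean and local background intensities of both channels are raw scanner values, per the file headers, and the processed intensities had the background subtracted and the dyes normalized by the scanner software, per the file headers. The deposited log10 ratio column is red over green of the processed intensities. The deposited series table holds log2 values, whose making is not given in the sources used here. Set against each array's scanner values, it equals log2 of processed red over processed green, that is hypomorph over wild type, with a correlation of 1 and no centring. Its column medians were -0.02, -0.00, -0.05 and -0.02, and its scale, centring and direction are thus settled. Spike-in controls gave slopes of observed against expected log ratios of 0.690, 0.716, 0.718 and 0.714 on the 4 arrays, so ratios are compressed. Between 4 and 8 spots per array were saturated in Cy5, and they were kept.

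From these files, the mean intensities were corrected with limma's normexp method (limma 3.58.1, R 4.3.3) with an offset of 50 and normalized within each array by loess with a span of 0.3 and a weight of 0 for control spots. Control spots and spots that the scanner software marked as outliers in the feature or its background were left out. Spots of a probe were averaged, and a probe was kept if it was well above background in at least 1 channel on at least 3 of the 4 arrays and had values on at least 3. This left 20611 genes, each represented by its brightest probe. Probe names are those of the array's design. Of 41174 probes, 24375 were renamed through a RefSeq accession in a gene table of assembly GRCm38.p6, and the others kept the name in the files. Probe positions are those in the files, in build mm8. Each gene's mean log2 ratio over the 4 arrays was tested against 0 with limma's moderated test and Benjamini-Hochberg adjustment, and a gene was called changed at an adjusted p under 0.05. With 4 arrays, the number of arrays limits the precision. Where no array showed a probe well above background in 1 genotype, the fold is given as a lower bound, the bright genotype's mean over the mean of, per array, the dim probe's own signal or the lowest signal that counted as well above background, whichever was higher. These signals are per channel after loess and Aquantile, and the bound is open to dye bias and to the scaling.

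Before the data were examined, 50 gene lists, the tests, the processing alternatives and a rule for the genes named were fixed. The rule took Fgf8, the 15 genes with the highest and the 15 with the lowest mean among those called with the same sign on 4 of 4 arrays, leaving out names that are accessions, clones or gene models, and up to 4 members of each list with the smallest p. It took 218 genes, of which 134 are named in the text, and which members of a list are named was decided after their values were seen, so the counts of how many genes held under the alternatives cover the rule's genes and not only those named. Of the 50 lists, 49 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01, over the 18549 genes with values on 4 of 4 arrays, and with an estimated correlation and fry beside it. No dye swap, probe sequence or second slide was at hand, so base composition and slide effects were not tested.

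The steps were tested on 10 simulated tables of 18549 genes over 4 arrays with the measured SDs and 200 changed genes each. Of the genes changed 1.5-fold, 78.3% were called, and of those changed 2-fold, 93.5%. Of all calls, 5.45% were false, and no changed gene was called with the wrong sign. No smaller change and no dye bias was simulated, and the changed genes were few, so this share of false calls need not hold for the data. In 10 simulated tables with 1 list of 25 genes shifted by 0.3 in log2 among 50, camera called the shifted list in 10, and it called 0.1 unshifted lists per table on average. The simulated genes were drawn independently and the lists at random. These simulated tables thus did not test the rate of false list calls where genes of a list move together. The counts of lists under other sign assignments of the arrays, given at the end, bear on it.

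The alternatives were the processed intensities, no or plain background subtraction, an offset of 16, median centring, scaling or Aquantile between arrays, the deposited series table, no filter or a stricter filter on dim probes, marked spots kept, other rules for genes with several probes, an intensity trend with robust variance, array weights, limma's treat against 1.2-fold, a fit of the separate channels with no array block, and each array left out in turn. A loess span of 0.1 and a version that ignored only the background outlier marks were added after seeing the data.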

Results

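To determine how reduced Fgf8 alters gene expression in the mouse lung shortly before birth, RNA from Fgf8 hypomorph lungs was compared with RNA from wild type littermate lungs at E18.5. Fgf8 encodes a secreted fibroblast growth factor, and the hypomorph genotype is written Fgf8H/- in the notes on sample preparation. The sample titles name it by other letters, whose meaning is not given in the sources used here, so the alleles of the pools are known from those notes alone. Lung lobes were dissected free of the large airways and vessels, and 3 lungs of a genotype were pooled for each RNA sample. Each of 4 two-colour arrays held 1 hypomorph pool labelled with Cy5 and 1 wild type pool labelled with Cy3, so that n = 4 pools per genotype. Of 43379 spots per array that were not controls, between 32491 and 33744 were well above background for the wild type and between 32731 and 34519 for the hypomorph. Ratios are given as log2 of hypomorph over wild type, as mean ± SD over the 4 arrays unless another n is stated. The dyes were never exchanged, so a dye effect on a single probe has the same sign as a genotype effect on every array.

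Fgf8 itself was measured by 1 probe well above background in both genotypes, at chromosome 19, 45790185 to 45790244 in mouse build mm8. Its log2 ratio was -0.18 ± 0.11, which is 1.13-fold lower, with single arrays at -0.31, -0.23, -0.09 and -0.09. The difference did not pass the threshold over all genes (limma, adjusted p = 0.0549), although the ratio lay below 0 on 4 of 4 arrays. Another Fgf8 probe was not well above background in either genotype. How the probe lies relative to the altered part of the Fgf8 alleles is not given in the sources used here, so its ratio does not measure the loss of working Fgf8. Under 4 alternative settings, counting the processed signals and the series table that repeats them once, the same probe passed, with log2 ratios between -0.25 and -0.15. Among FGF ligands and receptors there were 3 higher and 7 lower of 19 measured (adjusted over the list alone, 6 and 10). They included lower Fgf23 (-0.35 ± 0.05), Fgfr4 (-0.50 ± 0.16) and Fgf11 (-0.53 ± 0.20) and higher Fgfrl1 (0.29 ± 0.08), a receptor without a kinase domain. With the stricter filter on dim probes Fgf23 was not tested, and over the other alternatives its log2 ratio lay between -0.90 and -0.33. Among the genes that FGF and ERK signalling commonly switch on as feedback, there were 3 higher and 2 lower of 15 measured (adjusted over the list alone, 3 and 2). Dusp6, a phosphatase that acts on ERK, was lower (-0.42 ± 0.03, n = 3), whereas Etv1 (0.21 ± 0.05) and the antagonist Spry2 (0.23 ± 0.13) were higher. Without replicate 2, the adjusted p was 0.0506 for Fgf11, 0.0648 for Fgfrl1, 0.0593 for Dusp6 and 0.0928 for Etv1, and without replicate 3 it was 0.054 for Fgfrl1 and 0.0815 for Etv1. Spry2 missed the threshold without any 1 of the 4 arrays, with adjusted p between 0.0528 and 0.122. Neither list as a whole stood apart from the other genes (limma's camera, adjusted p = 0.549 and 0.401).

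Among single genes, the lowest ratio was that of Csta2, a gene of the stefin family of cysteine protease inhibitors, which was 6.96-fold lower in the hypomorph (-2.80 ± 0.73, adjusted p = 0.00278). Aspg, an asparaginase, was 4.72-fold lower (-2.24 ± 0.27), and Igfbp3, which binds insulin-like growth factors, was 3.02-fold lower (-1.59 ± 0.10). The chitinase-like genes Chil3 (-1.68 ± 0.38) and Chil4 (-1.24 ± 0.31) fell together, and so did the phospholipase Pla1a (-1.55 ± 0.05) and the sulphate transporter Slc13a4 (-1.54 ± 0.17). Kcnt1, Lhfpl3, Gipr, Amigo2, Ackr2, Lrp2, Ahsg and Amhr2 completed the 15 lowest, with mean log2 ratios between -1.49 and -1.19. In the opposite direction, Cntn1, a neural cell adhesion molecule, was 3.26-fold higher (1.70 ± 0.42, adjusted p = 0.00255), and Slitrk6, a transmembrane protein of neurons, was 2.81-fold higher (1.49 ± 0.12). The eosinophil chemokine Ccl11 (1.09 ± 0.10), the monocyte chemokine Ccl2 (0.89 ± 0.05), the bone matrix gene Ibsp (1.24 ± 0.19) and the globin Ngb (1.04 ± 0.17) also rose. Neither Defb37 nor Plppr1 was well above background in any wild type pool. Defb37 was at least 1.70-fold higher, and Plppr1 was 1.97-fold higher by the fitted ratio. The wild type signal of Plppr1 lay above the lowest signal counted as well above background on every array, so its bound is the fitted fold itself and no minimum. Its log2 ratio of 0.98 became 0.84 with median centring and reached 2.56 over the alternatives in which it was tested. That of Defb37 lay between 0.78 and 3.98 over such alternatives, so the size of both changes rests on the processing. The others of the 15 highest were Gcnt1, Sh2d4a, Olfr1410, Pramel48, Stag2, Defa3 and Pacs1. Pramel48 was not tested with the stricter filter on dim probes, and its log2 ratio lay between 0.86 and 2.07 over the other alternatives. Probes of a gene did not always agree. The second Cntn1 probe read 1.43 and the second Igfbp3 probe -1.90, close to the probes tested, whereas the other Aspg probe read -1.05, those of Lrp2 -0.80 and -0.25, those of Gipr -0.51 and -0.98, the other probes of Stag2 read -0.02 and -0.06, those of Gcnt1 -0.10 and -0.04, that of Pacs1 0.12, and those of Kcnt1 0.00 and -0.51. Gcnt1 also varied between arrays, from 0.61 to 3.03, and it did not pass without replicate 2 (adjusted p = 0.126) or without replicate 3 (adjusted p = 0.0661). Without replicate 2, the adjusted p was 0.0786 for Pramel48, 0.0532 for Plppr1 and 0.0788 for Ahsg, and without replicate 3 it was 0.0508 for Ahsg.

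**Figure D1:**
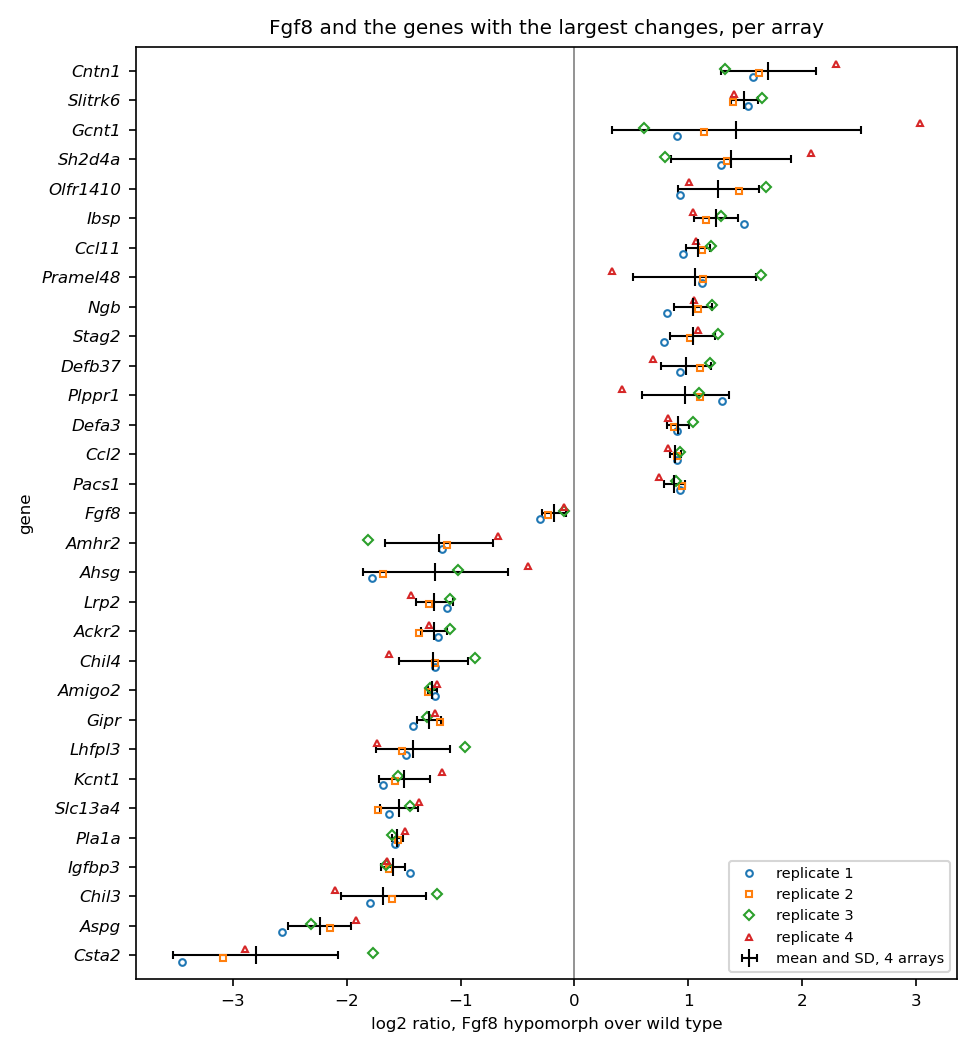
Log2 ratio of hypomorph over wild type (horizontal axis) of Fgf8 and of the 15 genes with the highest and the 15 with the lowest means among those that passed the test with the same sign on all 4 arrays, 1 gene per line, leaving out names that are accessions, clones or gene models. Symbols are the 4 arrays, vertical ticks the means and bars the SD. Of the genes drawn, Cntn1 has the highest mean, 1.70, and Csta2 the lowest, -2.80, while the 4 Fgf8 values lie between -0.31 and -0.09.

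Across the 20611 genes tested, 2880 were higher and 2728 lower in the hypomorph at an adjusted p under 0.05, and most of these changes were small, with a median size of 1.22-fold. Together they were 27.2% of the genes tested, the share against which counts within a list are to be read. Changes of at least 1.5-fold were more often decreases, with 167 genes higher and 278 lower, but this excess rests on the processing. The counts were 443 higher and 438 lower with Feature Extraction's processed signals, 385 and 383 with plain background subtraction, and 1030 and 152 with median centring. At least 2-fold changes numbered 21 higher and 37 lower. The count of 5608 changed genes fell to 1407 without replicate 2, 2044 without replicate 3 and 3587 without replicate 4, and was 5919 without replicate 1. When each array's ratios were centred on their median in place of loess normalization, 8335 genes were higher and 2443 lower, the median log2 ratio of all genes being 0.13, so the balance of higher and lower genes rests on the normalization. Of the genes named here, those lower after loess whose ratios then lay above 0 were Dusp6, Flt1, Tbx3, Sox17, Icam2, Atp1b1, Lpl, Krt19, Tagln and Srebf2. Loess left the ratios of the brightest probes above 0. The median log2 ratio was 0.27 over the 162 genes with a mean log2 brightness above 16, against values between -0.07 and 0.01 in the dimmer ranges.

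**Figure D2:**
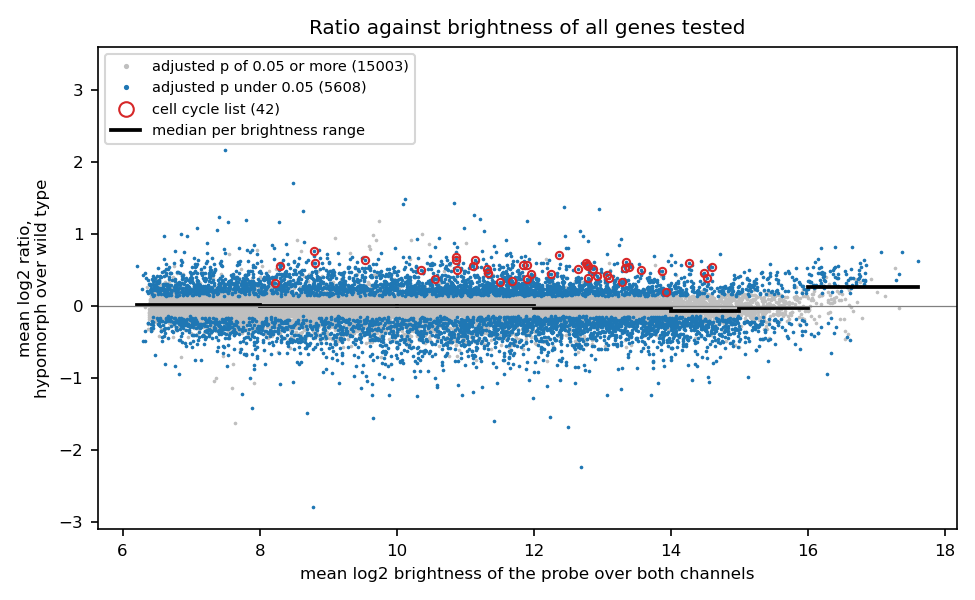
Mean log2 ratio of hypomorph over wild type (vertical axis) against mean log2 brightness over both channels (horizontal axis) for the 20611 genes tested, as means of 4 arrays. Blue points passed an adjusted p of 0.05, red circles are the 42 measured genes of the cell cycle list, and black lines are medians per range of brightness. The black line lies at 0.27 above a brightness of 16 and between -0.07 and 0.01 elsewhere.

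Genes of the cell cycle rose together in the hypomorph. Of the 42 measured, 41 were higher and none was lower (adjusted over the list alone, 42 higher), and the median log2 ratio was 0.52, with single arrays at 0.62, 0.50, 0.57 and 0.37. The members with the smallest p were the mitotic kinase Aurkb (0.64 ± 0.06), the replicative helicase subunit Mcm5 (0.71 ± 0.09), the replication licensing factor Cdc6 (0.77 ± 0.11) and the spindle checkpoint kinase Bub1 (0.55 ± 0.04). The list stood above the other genes with camera's preset correlation of 0.01 (adjusted p = 3.10e-21), but not with a correlation estimated from the 4 arrays (adjusted p = 0.602). The same holds for all 11 lists that camera called at the preset correlation, of which 10 were lower: none was called with an estimated correlation, and the smallest adjusted p was then 0.495. At the preset correlation, 18 lists were called without replicate 1. With the signs of replicates 3 and 4 turned, which cancels an effect equal on all arrays, camera called 14 lists. The direction of the cell cycle list held under every scaling tried, with medians from 0.46 to 0.78. Its count of higher genes was 42, 33, 37 and 40 without replicates 1, 2, 3 and 4 in turn and 34 with separate channels.

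Genes of the response to low oxygen and of glycolysis were lower in the hypomorph, although with median centring their median rose above 0, to 0.05, the call was lost (adjusted p = 0.0839) and 8 were higher and 8 lower. Under that centring the median of all genes was itself 0.13. Of the 28 measured, 18 were lower and none was higher (adjusted over the list alone, 18 lower), among them the glycolytic regulator Pfkfb3, 1.82-fold lower (-0.86 ± 0.08) by the probe tested and -0.24 by each of the other probes, the lipid droplet gene Hilpda (-0.67 ± 0.06), the vasodilator peptide gene Adm (-0.63 ± 0.06) and the mitophagy gene Bnip3 (-0.83 ± 0.13). The list's median was -0.25 (camera, adjusted p = 3.31e-06, and 0.495 with an estimated correlation). Among VEGF and angiogenic factors, 4 of the 24 measured genes were higher, 12 were lower and 8 did not pass the test (adjusted over the list alone, 5 higher and 13 lower). Adm belongs to this list too, and the others with the smallest p were Angpt2 (-0.49 ± 0.08), the endothelin gene Edn1 (-0.82 ± 0.20) and the VEGF receptor gene Flt1 (-0.43 ± 0.07). This list's median of -0.20 (camera, adjusted p = 0.03, and 0.602 with an estimated correlation) rose to 0.06 with median centring, with 10 higher and 7 lower, and its call was lost there (adjusted p = 0.436), without replicate 3 (adjusted p = 0.0674) and with an intensity trend and robust variance (adjusted p = 0.0549). It was also lost with marked spots kept (adjusted p = 0.0837) and with background marks ignored (adjusted p = 0.0852), where the median was -0.07. Of the immediate early genes, which respond within minutes to growth factors and stress, 15 of 26 were lower and 2 higher (adjusted over the list alone, 15 and 5), led by lower Ccn2 (-0.76 ± 0.08), Maff (-0.75 ± 0.08), Ier3 (-0.60 ± 0.09) and Sik1 (-0.55 ± 0.07). Their median was -0.21 (camera, adjusted p = 0.00255, and 0.609 with an estimated correlation), and 0.12 with median centring, with 10 higher and 6 lower. A list of glucocorticoid response genes, not all of them induced by the hormone, had a median of -0.18 (camera, adjusted p = 0.00621, and 0.609 with an estimated correlation), but 0.13 with median centring, and 2 of the 19 measured genes were higher, 10 were lower and 7 did not pass the test (adjusted over the list alone, 2 higher and 12 lower). Pdk4 (-0.80 ± 0.10), Sult1a1 (-0.55 ± 0.07) and Dusp1 (-0.47 ± 0.04) were lower, and Rgs2 was 1.76-fold higher (0.82 ± 0.05), at a brightness of 16.4 where most ratios lay above 0, while another Rgs2 probe read -0.055. With median centring the glucocorticoid genes counted 6 higher and 1 lower, and neither the immediate early list (adjusted p = 0.634) nor the glucocorticoid list (adjusted p = 0.962) was called. Without replicates 1, 2, 3 and 4 in turn, the number of lower genes was 16, 9, 12 and 14 in the hypoxia list, 13, 7, 9 and 10 in the VEGF list, 15, 9, 9 and 10 in the immediate early list and 12, 3, 4 and 6 in the glucocorticoid list. With separate channels it was 10, 8, 8 and 4. Of the measured genes, 10 of 19 of the glucocorticoid list and 11 of 24 of the VEGF list also belong to other lists. These lists are thus not independent of the others.

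In the epithelium, genes of the lung's salt and water transport were lower. Of the 20 measured, 10 were lower and 1 was higher (adjusted over the list alone, 12 and 1), with the water channel Aqp5 1.58-fold lower (-0.66 ± 0.06), the sodium channel subunits Scnn1g (-0.44 ± 0.04) and Scnn1a (-0.52 ± 0.10) and the sodium pump subunit Atp1b1 (-0.46 ± 0.10). The list's median was -0.19 (camera, adjusted p = 3.55e-04, and 0.495 with an estimated correlation). With median centring it was -0.02, the call was lost (adjusted p = 0.52) and 5 genes were higher and 0 lower. With the mean of all probes of a gene the median was -0.12. The lower genes numbered 10, 4, 8 and 7 without replicates 1, 2, 3 and 4 in turn, and 6 with separate channels. Aqp5 and Scnn1g also belong to the alveolar type 1 cell markers, where 1 of the 19 measured genes were higher, 9 were lower and 9 did not pass the test (adjusted over the list alone, 1 higher and 9 lower), including the basement membrane collagen Col4a4 (-0.57 ± 0.10) and Pxdc1 (-0.61 ± 0.15). That list, with a median of -0.15, was not called (camera, adjusted p = 0.0517), and its median turned to 0.21 with median centring. It was called, downward, under many other settings: the processed signals (adjusted p = 0.00417), an offset of 16 (0.0452), plain background subtraction (0.0308), no filter on dim probes (0.0193), the mean of all probes (9.55e-04), array weights (0.0442), separate channels (0.00602), a loess span of 0.1 (0.00194), replicate 1 left out (0.0238), replicate 2 left out (0.0235) and replicate 3 left out (0.024). Markers of alveolar type 2 cells, which make surfactant, went both ways, with 2 higher and 5 lower of 19 measured (adjusted over the list alone, 3 and 6). Pon1 was 2.35-fold lower (-1.23 ± 0.18, n = 3), Il33 (-0.60 ± 0.12, n = 3) and Chil1 (-0.53 ± 0.18) were also lower, although Il33 not without replicate 2 (adjusted p = 0.0525), and Egfl6 was higher (0.32 ± 0.09). Their median of 0.03 and mean of -0.13 differed in sign (camera, adjusted p = 0.585). The list was called upward with median centring (adjusted p = 0.00862). Several of the brightest epithelial genes had outlier marks on their spots and could be tested only with marked spots kept. With those spots kept, the surfactant protein gene Sftpd had a log2 ratio of -0.58 ± 0.21 and Sftpc one of 0.46 ± 0.17, at a brightness of 18.2. These genes were chosen after their values were seen. Club and secretory cell markers counted 2 higher and 4 lower of 15 measured (adjusted over the list alone, 2 and 4), with lower Fmo2 (-0.53 ± 0.11), Cyp4b1 (-0.57 ± 0.05, n = 3) and Scgb3a1 (-0.86 ± 0.58) and higher Cbr2 (0.45 ± 0.07), at a brightness of 17.3. The Cbr2 ratio rests on the normalization. It was 0.07 with the processed signals (adjusted p = 0.383) and 0.04 with a loess span of 0.1 (adjusted p = 0.549), but 1.33 with median centring. Of the neuroendocrine cell markers, 5 of 16 were lower and 1 was higher (adjusted over the list alone, 6 and 2), with lower ratios for the peptide genes Calcb (-0.57 ± 0.06) and Calca (-0.65 ± 0.22). Ciliated cell markers counted 2 higher and 1 lower of 24 measured (adjusted over the list alone, 1 and 0), and basal cell markers 1 higher and 1 lower of 6 measured (adjusted over the list alone, 1 and 1). Scgb3a1 did not pass without replicate 3 (adjusted p = 0.0943) or replicate 4 (adjusted p = 0.0973). None of these 3 lists was called (camera, adjusted p = 0.336, 0.0809 and 0.747). The ciliated list was called, upward, under 4 settings: median centring (adjusted p = 0.0203), no filter on dim probes (0.0337), replicate 3 left out (0.00204) and replicate 4 left out (0.0254).

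Markers of mesothelium, the lung's outer lining, were lower, with 9 of 13 lower and none higher (adjusted over the list alone, 12 lower) and a median of -0.37. With median centring the median was -0.092, with 4 lower and 1 higher, and the list was still called (adjusted p = 0.0209). Lrrn4 was 1.62-fold lower (-0.69 ± 0.25), followed by Krt19 (-0.31 ± 0.09), Bnc1 (-0.39 ± 0.14) and Aldh1a2 (-0.33 ± 0.11) (camera for the list, adjusted p = 2.98e-04, and 0.602 with an estimated correlation). Without replicate 2, Krt19 (adjusted p = 0.0615) and Bnc1 (adjusted p = 0.0618) did not pass. Pericyte markers had a median of -0.20, which turned to 0.02 with median centring, where 4 higher and 5 lower were counted, and 8 of 15 were lower and none higher (adjusted over the list alone, 9 lower). The paired potassium channel genes Kcnj8 (-0.87 ± 0.14) and Abcc9 (-0.77 ± 0.08) were lower, as were Trpc6 (-0.49 ± 0.05) and Rgs4 (-1.09 ± 0.37) (camera for the list, adjusted p = 5.86e-04, and 0.602 with an estimated correlation). Leaving out replicates 1, 2, 3 and 4 in turn gave 9, 5, 7 and 7 lower mesothelial genes and 9, 5, 6 and 6 lower pericyte genes, and separate channels gave 4 and 5. Smooth muscle and myofibroblast markers counted 2 higher and 8 lower of 19 measured (adjusted over the list alone, 3 and 9), with lower Hhip (-0.81 ± 0.14), Myocd (-0.43 ± 0.10) and Tagln (-0.32 ± 0.05). Endothelial cell markers counted 4 higher and 10 lower of 24 measured (adjusted over the list alone, 4 and 11) and had a median of -0.12, which became 0.28 with median centring, and their lower members included Sox17 (-0.49 ± 0.13) and Icam2 (-0.34 ± 0.07). Capillary and arterial markers counted 3 higher and 9 lower of 22 measured (adjusted over the list alone, 3 and 11), with Car4, the carbonic anhydrase of lung capillaries, 1.70-fold lower (-0.76 ± 0.15). Of these markers, 9 of 22 also belong to other lists. Among lymphatic markers, 2 of the 11 measured genes were higher, 4 were lower and 5 did not pass the test (adjusted over the list alone, 2 higher and 4 lower), with Lyve1 lower (-0.79 ± 0.07, and -0.28 by another probe) and the growth factor Vegfc higher (0.58 ± 0.09, n = 3). Camera called none of these 4 lists (adjusted p = 0.108, 0.0757, 0.147 and 0.0755). Other settings called them downward. For smooth muscle these were separate channels (adjusted p = 0.0426) and replicate 1 left out (0.0232). For the capillary list they were marked spots kept (adjusted p = 0.0476), background marks ignored (0.0496) and replicate 1 left out (0.0318), and for the lymphatic list no filter on dim probes (adjusted p = 0.0341), array weights (0.0389) and replicate 1 left out (0.0232). For the endothelial list they were the processed signals (adjusted p = 0.04995), the mean of all probes (0.0146), separate channels (0.0402) and replicate 3 left out (0.0399), while median centring called it upward (adjusted p = 0.0357). The matrix genes Fbn2 (0.73 ± 0.12) and Vcan (0.80 ± 0.15) were higher in a list of elastin and extracellular matrix genes that counted 4 higher and 1 lower of 27 measured (adjusted over the list alone, 4 and 1) (camera, adjusted p = 0.154), although the other Vcan probes read 0.22 and 0.33. With median centring this list was called, upward (adjusted p = 0.00146). Mesenchymal transcription factors and lipofibroblast markers counted 7 higher and 5 lower of 22 measured (adjusted over the list alone, 7 and 6), with higher Pth1r (0.39 ± 0.03) and Foxp2 (0.39 ± 0.11) and lower Lpl (-0.37 ± 0.08) and Tbx3 (-0.45 ± 0.04, n = 3), of which Tbx3 did not pass without replicate 2 (adjusted p = 0.0539) (camera, adjusted p = 0.154, and 0.00862, upward, with median centring).

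Of the blood cell lists, platelet and mast cell markers were lower under every scaling tried, with medians from -0.43 to -0.30. There were 1 higher and 10 lower of 18 measured (adjusted over the list alone, 1 and 10), including the mast cell proteases Cma1 (-0.46 ± 0.03) and Cpa3 (-0.48 ± 0.10) and the platelet genes Clec1b (-0.70 ± 0.20) and Gp9 (-0.81 ± 0.27). The list's median was -0.34 (camera, adjusted p = 0.00255, and 0.609 with an estimated correlation). The number of lower genes was 10, 4, 6 and 10 without replicates 1, 2, 3 and 4 in turn and 8 with separate channels. Macrophage and monocyte markers had a median of -0.16, or 0.10 with median centring with 8 higher and 3 lower, and counted 0 higher and 9 lower of 24 measured (adjusted over the list alone, 1 and 9), with lower Cd163 (-0.57 ± 0.06), C1qa (-0.32 ± 0.03) and C1qb (-0.25 ± 0.01) besides Chil3. C1qb did not pass without replicate 2 (adjusted p = 0.0572). Camera called this list (adjusted p = 0.0271, and 0.712 with an estimated correlation), but not without replicate 1 (adjusted p = 0.0572, median -0.10), with separate channels (adjusted p = 0.05002), with median centring (adjusted p = 0.615) or with the mean of all probes of a gene (adjusted p = 0.067, median -0.05). Its lower genes numbered 9, 3, 5 and 6 without replicates 1, 2, 3 and 4 in turn, and 2 with separate channels. Erythroid markers counted 1 higher and 5 lower of 23 measured (adjusted over the list alone, 1 and 6), lymphocyte and thymocyte markers 3 higher and 1 lower of 22 measured (adjusted over the list alone, 3 and 1), and neutrophil and granulocyte markers 1 higher and 1 lower of 14 measured (adjusted over the list alone, 1 and 1). None of these 3 lists was called (camera, adjusted p = 0.103, 0.216 and 0.855). The erythroid list was called, downward, under 2 settings: median centring (adjusted p = 0.0173) and replicate 1 left out (0.0318).

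Cardiac muscle markers were measured because heart muscle can lie next to dissected lung tissue. Their median was -0.53, and 9 of 27 were lower and none higher (adjusted over the list alone, 12 lower), among them Ryr2 (-0.53 ± 0.15), Cox8b (-1.06 ± 0.39), Pln (-0.75 ± 0.29) and Tnni3 (-0.75 ± 0.40). Tnni3 did not pass without replicate 3 (adjusted p = 0.069). The decrease was uneven, since the list's median was -0.13 and -0.12 on the arrays of replicates 1 and 2 and -0.67 and -0.91 on those of replicates 3 and 4 (camera, adjusted p = 4.17e-04, and 0.735 with an estimated correlation, and 0.154 with fry, which tests a list against no change and not against the other genes). The median over the remaining arrays was -0.54, -0.60, -0.41 and -0.29 without replicates 1, 2, 3 and 4 in turn. The number of lower genes was then 15, 8, 3 and 5, and with separate channels it was 3. Skeletal muscle markers counted 3 higher and 4 lower of 18 measured (adjusted over the list alone, 4 and 5). Of these, the muscle regulator Myod1 was 2.70-fold higher (1.43 ± 0.13, n = 3), whereas Neb (-0.76 ± 0.11) and Eno3 (-0.55 ± 0.16) were lower (camera for the list, adjusted p = 0.585, and 0.0132, downward, with median centring). Liver markers counted 0 higher and 5 lower of 12 measured (adjusted over the list alone, 0 and 6), with lower Rbp4 (-0.43 ± 0.13) and Ahsg (-1.22 ± 0.64) (camera, adjusted p = 0.121, and, downward, 0.0337 and 0.0344 without replicate 3 or 4 and 0.00159 with median centring). Of the sex-linked genes, 0 of 10 were called higher and 0 lower (adjusted over the list alone, 0 and 0).

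**Figure D3:**
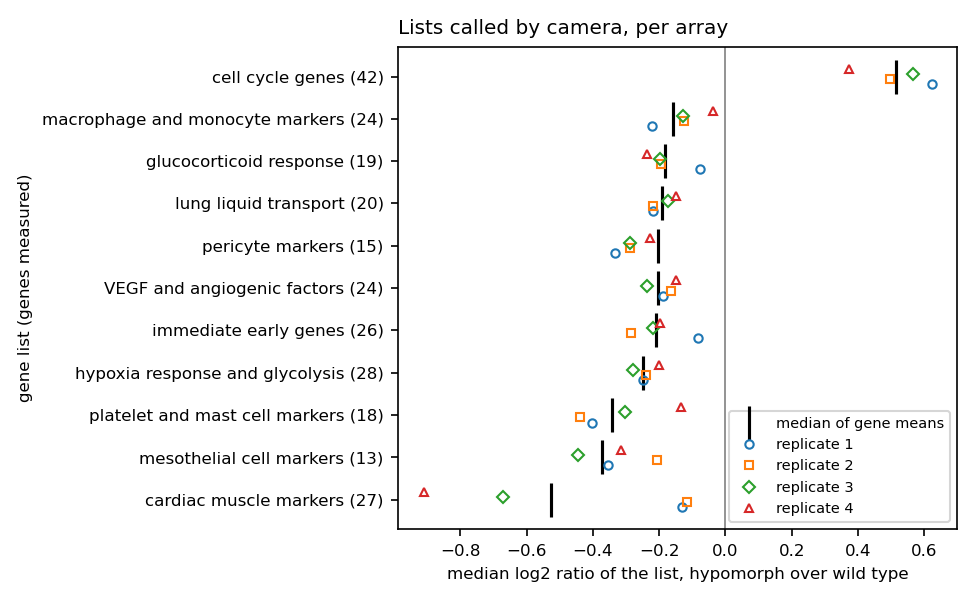
Median log2 ratio of hypomorph over wild type (horizontal axis) of the 11 gene lists that camera called at its preset correlation, with the number of genes measured in parentheses. Symbols are the medians on single arrays and black ticks the median of the gene means. Cell cycle genes lie between 0.37 and 0.62, and cardiac muscle markers between -0.91 and -0.12. With median centring the medians of the hypoxia, immediate early, glucocorticoid, VEGF, pericyte and macrophage lists lie above 0, as does the median of all genes (0.13).

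Of the WNT, hedgehog, Notch, TGF-beta and BMP, and retinoic acid lists, none was called, unlike the VEGF list above. Of all genes tested, 27.2% changed, so members that passed do not by themselves set a pathway apart. Among WNT pathway genes there were 7 higher and 7 lower of 32 measured (adjusted over the list alone, 7 and 11), with higher Rspo2 (0.67 ± 0.07) and lower Lef1 (-0.48 ± 0.13), Frzb (-0.52 ± 0.18) and Lgr5 (-0.34 ± 0.10). Hedgehog pathway genes counted 5 higher and 1 lower of 14 measured (adjusted over the list alone, 5 and 1): the receptor Ptch1 (0.35 ± 0.07) and the transcription factors Gli3 (0.44 ± 0.13) and Gli1 (0.24 ± 0.09) were higher, and the antagonist Hhip was 1.76-fold lower. Notch genes counted 2 higher and 4 lower of 20 measured (adjusted over the list alone, 4 and 4), with lower Dll4 (-0.32 ± 0.06) and Hey1 (-0.49 ± 0.11, n = 3) and higher Heyl (0.41 ± 0.14). TGF-beta and BMP genes counted 4 higher and 7 lower of 30 measured (adjusted over the list alone, 5 and 10). Retinoic acid genes counted 2 higher and 7 lower of 18 measured (adjusted over the list alone, 4 and 7), with Crabp1 higher (0.74 ± 0.11) and Aldh1a3 lower (-0.53 ± 0.15). The camera adjusted p for these 5 lists was 0.747, 0.194, 0.849, 0.35 and 0.401. Genes of sterol and fatty acid synthesis counted 8 higher and 2 lower of 28 measured (adjusted over the list alone, 11 and 2), with higher Fdps (0.31 ± 0.06), Mvk (0.29 ± 0.10) and Idi1 (0.23 ± 0.05), enzymes of the mevalonate pathway, and the regulator Srebf2 lower (-0.35 ± 0.05, n = 3), and a median of 0.09 (camera, adjusted p = 0.0509). That list was called, upward, under many other settings: the processed signals (adjusted p = 0.04995), no background subtraction (0.0499), an offset of 16 (0.0494), median centring (0.0025), no filter on dim probes (0.028), a stricter filter on dim probes (0.0464), an intensity trend and robust variance (0.0456), a loess span of 0.1 (0.0372), replicate 2 left out (0.0497) and replicate 4 left out (0.0254). Some of the genes named for these lists did not pass with 1 array left out. Without replicate 2 these were Lgr5 (adjusted p = 0.0566), Gli1 (0.0984), Hey1 (0.0671), Mvk (0.0764), Idi1 (0.0795) and Srebf2 (0.0811), without replicate 3 Gli1 (0.0857), Hey1 (0.0518), Mvk (0.0633), Idi1 (0.0695) and Srebf2 (0.0664), and without replicate 4 Gli1 (0.0566).

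For 43 of the named genes other probes were tested on their own, and for 24 of these at least 1 other probe read under 50% of the log2 ratio of the probe tested. For 14 genes no other probe passed in the same direction. Among members of the lists, other probes read 0.038 for Fdps, -0.16 for Fgf11, -0.22 and -0.14 for Fgfr4, -0.36, -0.12, -0.18 and -0.079 for Flt1, -0.06 for Lef1, 0.099 for Mvk, -0.20 for Myocd, 0.16 for Ptch1, -0.23 for Ryr2, -0.18 for Scnn1a, -0.42, -0.24 and -0.20 for Sox17 and -0.25, -0.071 and -0.067 for Srebf2. The other Tagln probe went the opposite way, at 0.12.

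Some named genes lost their call when the scaling or the choice of probes changed. With Feature Extraction's processed signals these were, besides Cbr2, Gcnt1 (1.68, adjusted p = 0.079), Spry2 (0.21, adjusted p = 0.102), Tnni3 (-0.52, adjusted p = 0.0784) and Scgb3a1 (-0.83, adjusted p = 0.0554). With the mean of all probes of a gene they were Gcnt1 (0.57, adjusted p = 0.134), Tagln (-0.16, adjusted p = 0.11) and Fdps (0.18, adjusted p = 0.0736). Plain background subtraction ended the calls of Gcnt1 (adjusted p = 0.0757) and Spry2 (adjusted p = 0.0559). An offset of 16 (adjusted p = 0.0567) and scaling between arrays (adjusted p = 0.0582) ended that of Gcnt1. With median centring, besides the genes given above whose ratios rose above 0, the genes were Fgfr4 (-0.12), Dll4 (-0.17), Hey1 (-0.0078), Aqp5 (-0.13), Col4a4 (-0.11), Scnn1g (-0.14), Fmo2 (-0.17), Cyp4b1 (-0.16), Sult1a1 (-0.18), Dusp1 (-0.18), Ccn2 (-0.18), Scnn1a (-0.012), C1qa (-0.15), C1qb (-0.17) and Aldh1a2 (-0.092).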

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

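The comparison of cell cycle genes with blood cell lists was chosen only after the result was seen, and so was the bound a bootstrap interval had to clear to argue against dye bias. Of 85 results with 4 arrays that were examined for a single array far from the others, 4 had one, and chance alone gives about 1 in 20. Igfbp3 had a log2 ratio of -1.44 on the array of replicate 1 and between -1.66 and -1.63 on the others. Alveolar type 2 cell markers had a median of -0.077 on the array of replicate 2 and between 0.04 and 0.06 on the others. Mesenchymal transcription factors and lipofibroblast markers had a median of 0.21 on replicate 1 and between 0.02 and 0.04 on the others. The spike-in slope was 0.690 on replicate 1 and between 0.714 and 0.718 on the others.

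Cell cycle genes were higher in the hypomorph on every array. A dye effect on single probes would leave the other probes of these genes near 0, but 21 other probes of 16 of the genes had a median log2 ratio of 0.35 (95% bootstrap interval 0.20 to 0.57), with 95.2% of them above 0. More dividing blood cells in the hypomorph pools would raise blood cell markers as well. The highest upper bound among the medians of 4 blood cell lists was 0.11, below the 0.26 that is 50% of the cell cycle median. The erythroid list had a median of -0.06 (95% bootstrap interval -0.20 to -0.01), and its member Alas2 (-0.22) was lower. The globins Hba-a1 (0.69) and Hbb-bt (0.41), measured only with marked spots kept, lay above 0.26. Their brightness was near 18, and the genes tested above a brightness of 16 had a median of 0.27. This explanation thus stays open for red blood cells. A ratio trend with brightness was tested with 10000 random lists matched on brightness, of which 0 reached the cell cycle median and the highest reached 0.12. More dividing cells of the lung itself remain another candidate explanation, untested apart from blood cells on arrays in which dye and genotype run together.

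Genes at least 1.5-fold apart behaved differently by direction. For the 278 lower genes, 125 other probes of 91 of them had a median of -0.42 (95% bootstrap interval -0.50 to -0.34), against -0.71 for the probes tested, and 89.6% went the same way, which argues against dye bias of single probes as the whole cause. For the 167 higher genes, 68 other probes of 48 of them had a median of only 0.12 (95% bootstrap interval 0.05 to 0.24), against 0.66 for the probes tested, and 76.5% went the same way. Much of the list of higher genes may thus rest on single probes, through dye bias or through sequences that only 1 probe detects, which these arrays do not separate. The genes of both directions were selected by the ratios of the probes tested, each the brightest of its gene. Other probes can read smaller ratios in part for that reason alone. Genes with a single probe were not covered by this test.

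Cardiac muscle markers were lower to a different degree on different arrays. The SD of the list's median over the 4 arrays was 0.40, the largest of all lists, while the highest of 10000 random lists matched on brightness had 0.14. Random lists of unrelated genes average out, however. The interferon response (0.24) and club cell (0.24) lists also exceeded 0.14, although the random lists were not matched to them. Club, ciliated and basal cell medians were, like the cardiac median, lower on the arrays of replicates 3 and 4 than on those of 1 and 2. Whether dissection moved these lists too was not tested, so they are no control for it. This spread thus does not decide whether the pools held unequal amounts of cardiac muscle. Of the 5 brightest members, Myh7 had a log2 ratio of -0.06 ± 0.18, Myl7 -0.55 ± 0.46 (n = 3), Tnnt2 -0.19 ± 0.34, Myl4 -0.29 ± 0.43 and Myh6 -0.13 ± 0.36. None of the 27 measured members belongs to another list, and all were detected in these pools. These values do not separate unequal dissection from a change of cardiac muscle tissue in the hypomorph itself, and both stay open.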

How the results depend on the processing

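A loess span of 0.1 and the version that ignored background outlier marks were chosen after seeing the data. The slide block was not run, since all arrays lay on 1 slide, nor was the regression on base composition, since probe sequences were not used here. The ratio of each array already pairs 1 pool of each genotype, and the fit of separate channels with no array block is the unpaired form. The rule for named genes took 218 genes, of which 197 passed the test. Aquantile left all ratios as they were and the series table repeats the processed signals, so neither is counted in what follows. Of the 4131 values of these genes under the other alternatives, 3675 kept their direction and their side of the threshold, 433 no longer passed and 23 reversed, and 59 of the genes kept both under all alternatives run. Treat against 1.2-fold ended 132 of these calls, separate channels ended 76, median centring ended 26 and reversed 23, and 7, 71, 46 and 25 were lost without replicates 1, 2, 3 and 4 in turn. Signal over background limits what was tested, since 31354 of 41174 probes passed the filter on dim probes.

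The 5608 changed genes became 10778 with median centring, 341 with treat and 1399 with separate channels, and ranged from 1407 to 5919 with 1 replicate left out. The 445 genes changed at least 1.5-fold became 881 with the processed signals and with the series table, 768 with plain background subtraction, 1182 with median centring and 246 with treat, and ranged from 335 to 569 with 1 replicate left out. Of these 445 genes, 406 stayed changed in the same direction with the processed signals, 433 with median centring and 322 without replicate 2. The Fgf8 log2 ratio passed at -0.25 with the processed signals and with the series table, -0.20 with no background subtraction, -0.17 with scaling between arrays and -0.15 with array weights, with adjusted p over all alternatives but treat between 0.0375 and 0.296. It ranged from -0.21 to -0.135 with 1 replicate left out. The 11 called lists became 18 with median centring and 0 with an estimated correlation, and ranged from 13 to 18 with 1 replicate left out. Fry asks whether a list changed at all, which is another question, and called 19 lists, cardiac muscle not among them (adjusted p = 0.154). Cell cycle, pericyte, mesothelial, and platelet and mast cell lists stayed called under all alternatives run for lists but the estimated correlation, although the pericyte median rose to 0.02 with median centring. Lists were not tested with treat or with every probe on its own. Of 38 lists not called, 20 were called by camera under at least 1 alternative, 13 of them with 1 replicate left out. Fry is not counted there, and it called FGF ligands and receptors, downward (adjusted p = 0.00914).

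With median centring, the glucocorticoid list lost its call (camera, adjusted p = 0.962). Its median of 0.13 was then level with the median of all genes, also 0.13. Besides the pericyte median, those of the hypoxia (0.05), immediate early (0.12), VEGF (0.06) and macrophage (0.10) lists rose above 0 there, but not above the median of all genes. Among the genes named, the log2 ratios that rose above 0 were those of Dusp6 (0.23), Flt1 (0.034), Tbx3 (0.14), Sox17 (0.036), Icam2 (0.22), Atp1b1 (0.069), Lpl (0.014), Krt19 (0.14), Tagln (0.13) and Srebf2 (0.086). Of these, only Dusp6, Tbx3, Icam2 and Krt19 exceeded the median of all genes. The cause was not tested. Treat asks for more than a change from 0, which lowers counts by its construction.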

Other observations

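The genes measured with marked spots kept and the counts at an unadjusted p were chosen only after results were seen. Among cytokines, chemokines and their receptors there were 9 higher and 4 lower of 26 measured (adjusted over the list alone, 9 and 5). Ccl2 and Ccl11, given among the highest genes, rose, while Cxcl14 (-0.60 ± 0.13) and Ccl6 (-0.47 ± 0.14) fell. Target genes of p53 counted 2 higher and 7 lower of 20 measured (adjusted over the list alone, 2 and 8), with the cell death gene Pmaip1 lower (-0.73 ± 0.05) and the mitotic gene Gtse1 higher (0.47 ± 0.09). Circadian clock genes counted 0 higher and 6 lower of 17 measured (adjusted over the list alone, 2 and 7), with lower Bhlhe40 (-0.58 ± 0.09, n = 3). The medians of the p53 and clock lists, -0.085 and -0.14, turned to 0.14 and 0.11 with median centring. Cartilage markers counted 5 higher and 0 lower of 13 measured (adjusted over the list alone, 5 and 1), with Matn4 higher (0.23 ± 0.04), which did not pass without replicate 2 (adjusted p = 0.0743) or replicate 3 (adjusted p = 0.0662). Camera called none of these 4 lists (adjusted p = 0.401, 0.0755, 0.147 and 0.147), although it called the clock list, downward, without replicate 1 (adjusted p = 0.0232). It called the p53 list, downward, under 5 settings: no filter on dim probes (adjusted p = 0.0337), marked spots kept (0.0215), array weights (0.0496), background marks ignored (0.022) and replicate 1 left out (0.0318). Interferon response genes had medians of -0.04, -0.00, -0.21 and 0.36 on the 4 arrays, and counted 3 higher and 2 lower of 32 measured (adjusted over the list alone, 0 and 0). That list was not called (adjusted p = 0.585) except, upward, without replicate 3 (adjusted p = 0.0337).

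Cytosolic ribosomal protein genes counted 10 higher and 0 lower of 26 measured (adjusted over the list alone, 11 and 1), led by Rpl6 (0.55 ± 0.07) and Rpl3 (0.82 ± 0.16), which have a mean log2 brightness of 16.1 and 16.6. Camera did not call the list (adjusted p = 0.121), but it did, upward, without replicate 1 (adjusted p = 0.0211), replicate 3 (adjusted p = 0.0385) or replicate 4 (adjusted p = 0.0127), with separate channels (adjusted p = 0.0426) and with median centring (adjusted p = 9.51e-05). With marked spots kept, the measured members rose from 26 to 39, of which 27 were higher, the median was 0.53 and the list was called (adjusted p = 1.05e-11), as it was with background marks ignored (adjusted p = 7.57e-12). The median of 0.18 without marked spots lies below the median of 0.27 of the genes tested above a brightness of 16. These sets were not matched on brightness, so the comparison does not decide whether the rise follows brightness. Antioxidant genes counted 3 higher and 7 lower of 21 measured (adjusted over the list alone, 3 and 7), respiratory chain genes 6 higher and 0 lower of 34 measured (adjusted over the list alone, 6 and 0), heat shock proteins 3 higher and 0 lower of 15 measured (adjusted over the list alone, 2 and 0), neuron and glia markers 1 higher and 0 lower of 15 measured (adjusted over the list alone, 0 and 0) and oesophagus markers 1 higher and 0 lower of 9 measured (adjusted over the list alone, 1 and 0), and camera called none of these lists (adjusted p = 0.35, 0.405, 0.154, 0.791 and 0.747). With median centring it called the respiratory chain (adjusted p = 2.67e-06) and heat shock (adjusted p = 0.00426) lists, upward. Of the 658 genes tested only with marked spots kept, several are among the brightest on the arrays. With those spots kept, the log2 ratio was 0.69 ± 0.04 for Hba-a1, 0.41 ± 0.21 for Hbb-bt, 0.29 ± 0.20 for Lyz2, 0.49 ± 0.12 for Mfap4 and -0.16 ± 0.06 for Scgb1a1. These 5 genes were chosen after their values were seen.

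Because the Fgf8 alleles and the strain background may be linked, genes near Fgf8 could differ between the pools through strain variants, a hypothesis that predicts more changed genes near Fgf8 on chromosome 19. Of 132 genes within 5 Mb of Fgf8, 40 changed, or 30.3%, against 27.2% elsewhere (permutation test, one-sided, p = 0.245), and 3 of them changed at least 1.5-fold. The test did not show an excess near Fgf8 and does not exclude a small excess, so the hypothesis stays open. In the list of genes that adjoin Fgf8 there were 5 higher and 3 lower of 25 measured (adjusted over the list alone, 6 and 3) (camera, adjusted p = 0.405, and 0.0482, upward, with median centring).

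The 4 arrays allow 8 assignments of signs, too few for a share under 0.05. The real assignment gave 5608 changed genes and 445 changed at least 1.5-fold, and 1 of the 8 gave as many in both counts, namely the real assignment. The highest of the others was 0 for limma's adjusted p, with 61 to 754 genes at an unadjusted p under 0.05. For gene lists, 4 of the 8 assignments gave at least the 11 lists of the real one, and the highest of the others gave 21, with replicate 1 turned against replicates 2, 3 and 4. With replicates 2 and 3, 2 and 4, or 3 and 4 turned against the other arrays, an effect equal on all arrays cancels. These assignments gave 1, 11 and 14 lists, though 0 genes passed. At its preset correlation, camera can thus call as many lists without such an effect. The number of lists called does not by itself show a genotype effect.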
